A study of Homo sapiens with 18 samples.

How the data were processed

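RNA was sequenced from MCF7 cells, an estrogen receptor-positive human breast cancer line, and from the extracellular vesicles (EVs) they release. Cells and EVs came from vehicle-treated cultures (dimethyl sulfoxide, DMSO, at 0.2%) and from cultures given 10 µM GW4869 or 5 µM FTY720. GW4869 inhibits neutral sphingomyelinase. FTY720 (fingolimod) is a sphingosine analog that acts on sphingosine 1-phosphate receptors after phosphorylation and also lowers acid sphingomyelinase activity. Vehicle samples are labeled untreated in 1 field and DMSO in the sample names, which were followed. The medium was MEM with 10% fetal bovine serum. Total RNA was extracted with TRIzol and depleted of ribosomal RNA, and libraries were made with the KAPA RNA HyperPrep kit with RiboErase. Cell libraries used 1 µg of RNA and drug-treated EV libraries 2 to 6 ng, with no input stated for DMSO EVs. Libraries had 7 and 16 PCR cycles, and the labels do not say which libraries had which. Sequencing was paired-end on a NovaSeq instrument.

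The submitters' processing notes name FastQC for read quality, STAR for alignment to GRCh38 (hg38) and DESeq2 for differential expression, without versions. The counting tool, its strand setting and the annotation release are not given in the sources used here. The deposited table holds raw counts per gene symbol, not normalized, for 18 libraries and 59385 gene names, of which 22153 were never counted. No sample column was left out. Gene positions and types came from GENCODE release 29 on GRCh38. 37762 gene names matched it directly and another 2449 through an Ensembl identifier, and the matched genes held 98.6% of all counts. Where a gene overlaps another on the opposite strand, or has near-identical copies, counts cannot be assigned with certainty. This concerns the antisense transcripts, host genes of microRNAs, processed pseudogenes, and histone and 7SL copies in the text.

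The 18 libraries form 6 groups of 3: cells and EVs, each under DMSO, GW4869 and FTY720. The labels do not say whether the 3 replicates of a group are separate cultures, so p-values measure the spread between these samples, which may be technical in part. Replicate numbers did not pair samples across groups and no pairing was used. Total counts ranged from 23473521 to 30121441 per cell library and from 15859090 to 22709790 per EV library. Intervals and floors cover counting error only, since reads carried no molecular identifiers. Between any 2 replicates of a group, counts differed by more than sampling noise, with chi-squared per degree of freedom of 2.65 to 26.7.

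Differential expression used edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr, libraries were scaled by TMM, and group means were compared with robust quasi-likelihood tests. Tests were 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Drug comparisons within cells or within EVs were fitted on the 9 libraries of that compartment. EV-against-cell comparisons and differences of a drug effect between EVs and cells were fitted on all 18. Standard errors (SE) of log2 fold changes are the log2 fold change divided by the square root of the F statistic. Levels of genes are TMM-scaled CPM and summed levels of lists are CPM without TMM factors, as mean ± SD over the 3 libraries of a group. A fold against a group with all libraries at 0 is a lower bound by counting error alone, computed with 3 counts per library. It is written as "at least". TMM scaling compares each gene with the bulk of the genes, so no change in total RNA per cell or per vesicle can be read from it.

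In all, 38 gene lists covering lipid metabolism, stress and signaling responses, vesicle biology, RNA classes and markers of other cell types were written before the data were examined, as were the comparisons, the tests, the rule for naming genes and most alternatives. A list was tested where at least 5 members were in the fit: 30 lists in the cell fit, 29 in the EV fit and 30 in the joint fit. The test was camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Each call was repeated with an estimated correlation, a stricter test that allows for genes of a list moving together, and calls that ended are given with that p. Counts of list members past the threshold refer to adjustment over all genes tested, and counts adjusted over the list alone are given where they differ. fry (limma) asks whether the genes of a list move on balance in 1 direction and does not compare the list with other genes.

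Named genes were taken from features past the threshold that carry a gene symbol, are not pseudogenes, have a mean of at least 5 CPM in the higher group and have every library of 1 group above every library of the other. Chance alone separates 3 libraries from 3 others for 10% of genes. For the effect differences, the effects had to differ by at least 1 on the log2 scale instead. The 8 largest rises and 8 largest falls were taken in the main comparisons, and 5 of each in comparisons between drugs, between EVs and cells under a drug, and between effects. Up to 4 members per list past the threshold with the largest changes were added. The sphingomyelinases SMPD1 to SMPD4, the sphingosine kinases SPHK1 and SPHK2 and the receptors S1PR1 to S1PR5 were always included where in the fit.

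Shares of counts in 6 RNA classes were compared with 2-sided exact permutation tests, with Benjamini-Hochberg adjustment over the 6. For 3 libraries against 3 such an exact test cannot go below p = 0.1. Overlap between drug responses was set beside the number given by independence and beside 20 simulations. In these, 2 unchanged groups shared the real DMSO libraries, as both drugs did. Agreement between EV and cell responses was measured across genes, which are not independent replicates.

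The alternatives were RLE (DESeq2-type) size factors, total count scaling, no filter and a stricter filter (1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom with quality weights, removal of abundant noncoding RNA and histone genes, thinning to the smallest library, a replicate block, all 18 libraries in the fit, and leaving out each library in turn. 3 alternatives were added after seeing the data: only the 6 libraries of the 2 groups compared, a mean of at least 10 CPM, and TMM factors from coding genes above 10 CPM in both compartments. On counts simulated with mean levels and spread pooled over the real libraries, edgeR recovered 50.7% of 2-fold changes between DMSO EVs and cells. For GW4869 it recovered 76.1% in cells and 56.7% in EVs. Its false share of calls was 1.56 to 7.78%. Rates at each group's own spread, widest in GW4869 EVs, were not tested. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for shares, sequence searches and plots.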

Results

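Counts per gene were obtained for 18 libraries of MCF7 cells and EVs, 3 per group. Total counts per library ran from 25796671 to 30121441 in DMSO cells, from 26710962 to 29446495 in GW4869 cells and from 23473521 to 27114320 in FTY720 cells. In EVs they ran from 20325000 to 22256133 under DMSO, from 19369386 to 22241445 under GW4869 and from 15859090 to 22709790 under FTY720. A gene with 0 counts in a library could thus have been present at up to 0.0996 to 0.189 CPM (3 counts). The 10 most counted genes held 6.34% ± 0.34 (SD, n = 9) of the counts of cell libraries and 15.3% ± 3.62 of the counts of EV libraries. Thinned to equal depth, EV libraries held 21268 ± 2006 genes above 0 under DMSO, 18432 ± 854 under GW4869 and 22685 ± 98.5 under FTY720 (SD, n = 3). Spread between replicates was widest in GW4869 EVs, with a biological coefficient of variation of 0.527, against 0.187 in DMSO EVs, 0.0566 in FTY720 EVs and 0.0398 in DMSO cells. Over genes with a mean of at least 10 CPM the values were 0.145, 0.1, 0.0539 and 0.0384, and under 10 CPM they were 0.977, 0.466, 0.1165 and 0.0791.

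EVs and cells differed in RNA classes, but compartment cannot be told apart from RNA input or PCR cycles. Transcripts of the mitochondrial genome made up 2.71% ± 0.302 (SD, n = 9) of cell counts and 0.109% ± 0.0492 of EV counts. The exact permutation p was 4.1e-05, the smallest it can give (adjusted p = 6.17e-05 over 6 classes). 7SL RNA, the RNA of the signal recognition particle, made up 0.844% of cell counts and 3.61% of EV counts (exact permutation p = 8.23e-05, adjusted p = 9.87e-05), and ribosomal protein mRNAs 2.94% and 6.43% (exact permutation p = 4.11e-05). The 7SL share of EVs was 3.13% ± 0.994 (SD, n = 3) under DMSO, 1.40% ± 0.385 under GW4869 and 6.30% ± 0.478 under FTY720. Replication-dependent histone mRNAs made up 0.305% of EV counts under DMSO, 0.182% under GW4869 and 1.198% ± 0.022 under FTY720, and 0.316%, 0.221% and 0.191% of cell counts. Over all libraries the histone share did not differ between EVs and cells by the test used (exact permutation p = 0.0994). Exact tests of 3 libraries against 3 cannot go below p = 0.1. Other small noncoding RNAs made up 0.793% of cell counts and 0.343% of EV counts. Ribosomal RNA genes, depleted before sequencing, held 0.00016% and 0.0000365%.

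**Figure D1:**
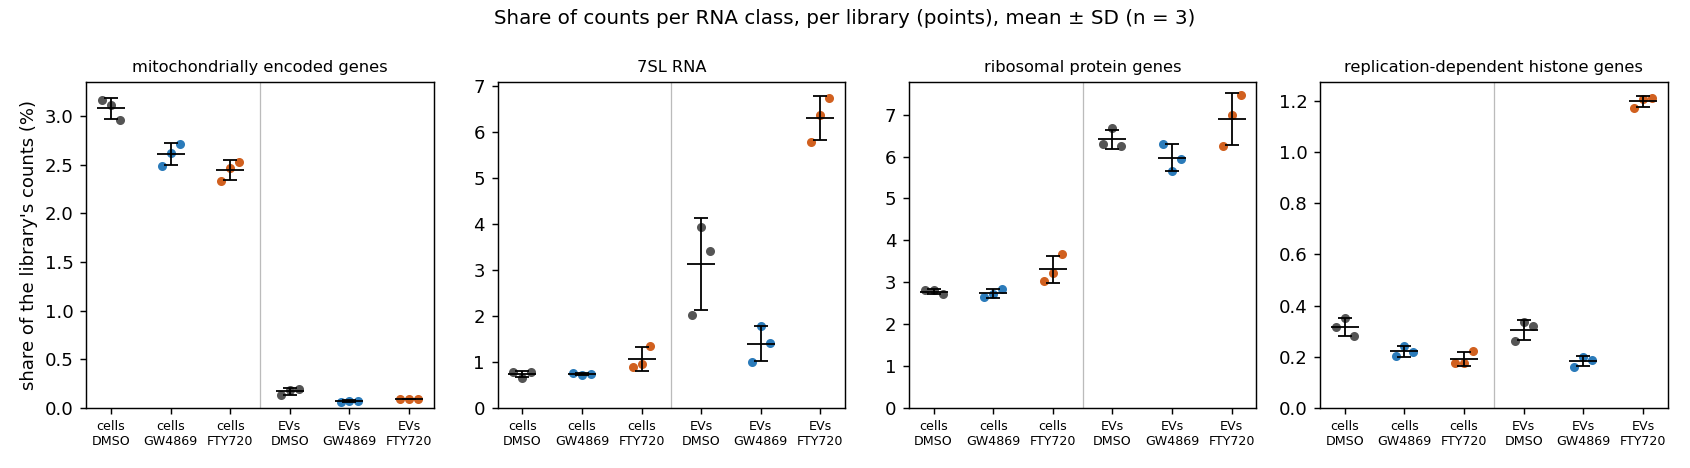
Share of each library's counts (%) in 4 RNA classes, for the 6 groups. Points are libraries, and bars give the mean and SD of 3; the 9 EV libraries lie below the 9 cell libraries for mitochondrially encoded genes (means 0.109% and 2.71%), and FTY720 EVs have the highest histone share (1.198%).

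The first comparison asked which RNAs were higher or lower in EVs than in cells under DMSO. RAB13, a small GTPase of vesicle traffic (chromosome 1, 153981617 to 153986358, GRCh38), went from 0.406 ± 0.102 CPM in cells to 538 ± 6.63 CPM in EVs (SD, n = 3), a log2 fold change of 10.37 ± 0.15 (SE, adjusted p = 1.61e-22). NET1, a guanine nucleotide exchange factor for RhoA (chromosome 10, 5412551 to 5458463), went from 228 ± 7.89 to 73740 ± 3197 CPM, a log2 fold change of 8.34 ± 0.07. TRAK2, an adaptor that links mitochondria to kinesin (chromosome 2, 201377207 to 201451579), was 327-fold higher at 19020 ± 458 CPM. KIF1C, a kinesin motor (chromosome 17, 4997948 to 5028401), was 252-fold higher at 22370 ± 1955 CPM. WDR87, C22orf46, KIF1C-AS1 and FBXL19-AS1 completed the 8 largest rises, at 348-, 236-, 236- and 207-fold. KIF1C-AS1 overlaps KIF1C on the opposite strand, and its counts may stem from KIF1C in part.

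Among the largest falls were the mitochondrial transcripts MT-ATP8, a subunit of ATP synthase, with a log2 fold change of −6.28 ± 0.38, and MT-ND6, a subunit of complex I, with −6.10 ± 0.25 (n = 3 per group). The mitochondrial threonine tRNA MT-TT had 0 counts in the 3 DMSO EV libraries and was at least 27.0-fold lower than in cells. RNF32-AS1 was 87.0-fold lower, and B3GALT5, a galactosyltransferase, 58.9-fold lower. SNORD3A, the U3 small nucleolar RNA, and the long noncoding RNAs LINC02666 and LINC02147 were 48.4-, 51.3- and 48.4-fold lower.

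Messages for the protein synthesis machinery were higher in EVs. Of 79 cytosolic ribosomal protein genes, 75 were higher and 0 lower (median log2 fold change 1.75, camera adjusted p = 3.55e-39, adjusted p = 0.131 with an estimated correlation). Of 28 translation factors 27 were higher, among them EIF3A at 5.07 ± 0.06 and the poly(A)-binding protein PABPC1 at 2.73 ± 0.05 (median 1.60, adjusted p = 4.78e-27). RNA-binding proteins tied to vesicle loading were higher for 16 of 21 genes and lower for 1, or 17 and 2 adjusted over the list alone, with nucleolin (NCL) at 4.70 ± 0.06, AGO1 at 15.9-fold and YBX1 at 2.82 ± 0.07 (median 0.79, adjusted p = 8.37e-09). Nuclear-encoded respiratory chain subunits were higher for 53 of 64 genes and lower for 4 (median 0.97, adjusted p = 4.28e-08, adjusted p = 0.348 with an estimated correlation). The heat shock response was higher for 9 of 12 genes, with the chaperones HSPD1 at 2.57 ± 0.06 and HSP90AA1 at 1.94 ± 0.07 (adjusted p = 6.41e-06, adjusted p = 0.0633 with an estimated correlation).

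Mitochondrially encoded genes were lower in EVs for 27 of 29 genes and higher for 1 (median −3.80, or −3.58 with genes at 0 set to their bounds, adjusted p = 2.03e-09, adjusted p = 0.0633 with an estimated correlation). Of 9 nuclear-retained long noncoding RNAs 7 were lower and 2 higher (median −2.12, adjusted p = 6.41e-06), with MALAT1 at −3.57 ± 0.09, NEAT1 at −2.61 ± 0.13 and FTX at −3.61 ± 0.15. Estrogen receptor targets were lower for 18 of 25 genes and higher for 3 (median −0.80, adjusted p = 0.00746, adjusted p = 0.278 with an estimated correlation). The corepressor NRIP1 was lower at −4.46 ± 0.14 and cyclin D1 (CCND1) higher at 3.03 ± 0.06. YAP and TEAD targets were lower for 9 of 13 genes (adjusted p = 0.00689, adjusted p = 0.0633 with an estimated correlation), and small nucleolar and Cajal body RNAs for 5 of 7 (adjusted p = 0.0392, adjusted p = 0.278 with an estimated correlation). Spliceosomal and U7 snRNAs did not pass, with 3 of 20 genes higher and 7 lower (adjusted p = 0.472), nor did small noncoding RNAs of cytoplasmic and Pol III RNPs, with 2 of 7 higher and 2 lower (median −0.64, test above 0, adjusted p = 0.964). Vesicle formation and release machinery did not pass as a list, with 19 of 42 genes higher and 10 lower (adjusted p = 0.132). The annexin ANXA2 was higher at 1.54 ± 0.06 and flotillin FLOT1 at 1.29 ± 0.11. The sphingolipid metabolism list did not pass either, with 8 of 37 genes higher and 20 lower (adjusted p = 0.119).

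In all, 12772 of 19495 genes differed between DMSO EVs and cells, 6081 higher and 6691 lower in EVs, and 3573 and 4505 of these by at least 2-fold. Cell cycle, p53 target, oxidative stress and histone genes also passed as lists, with medians of 0.63 to 0.79 and adjusted p of 0.131 to 0.721 with an estimated correlation, and the histone median of 0.63 turned to −0.06 under total count scaling. Of 30 lists 14 passed camera, and the 3 that held with an estimated correlation were translation factors, RNA-binding proteins and nuclear-retained long noncoding RNAs. Total count scaling moved the median of all genes to −0.776 and gave 3069 genes higher and 10503 lower, and it ended the calls of p53 targets and small nucleolar RNAs, the latter also lost with a replicate block. A mean of at least 10 CPM, which tests fewer genes, gave 8056 genes.

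**Figure D2:**
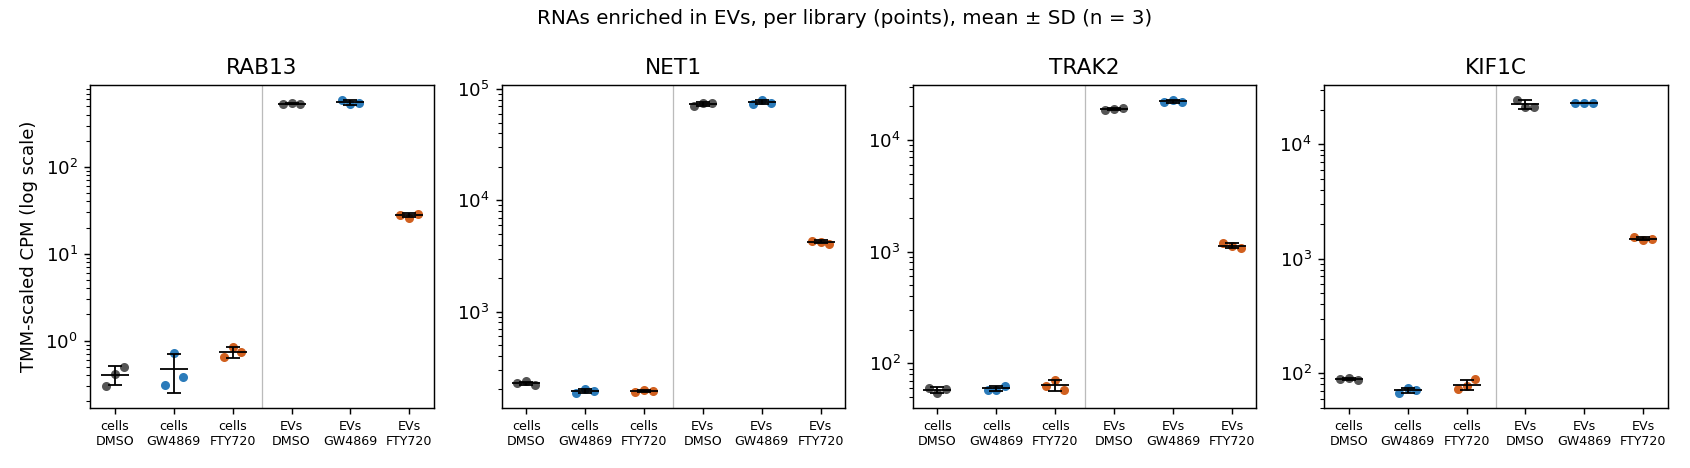
TMM-scaled CPM (log axis) of RAB13, NET1, TRAK2 and KIF1C in the 6 groups. Points are libraries, with the mean and SD of 3; all 4 mRNAs are higher in EVs than in cells in every library, and lower in FTY720 EVs than in DMSO or GW4869 EVs.

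Under GW4869 the comparison of EVs with cells asked whether the inhibitor leaves EV enrichment in place. The mRNAs with the largest enrichment were still far above their cell levels: RAB13 by 1172-fold (log2 fold change 10.20 ± 0.15 SE, n = 3 per group), NET1 by 392-fold, TRAK2 by 370-fold, C22orf46 by 326-fold and KIF1C by 326-fold. LINC02666 and LINC02803, noncoding RNAs, the transcript ZKSCAN2-DT and the mRNA MINAR2 had 0 counts in the GW4869 EV libraries and were at least 64.7-, 30.7-, 31.4- and 49.1-fold lower than in GW4869 cells. MIR3648-2, also at 0 in EVs and at least 31.7-fold lower, lost its call without GW4869 EV replicate 3 and in limma-voom, and its cell level varied between libraries (6.16 ± 9.38 CPM). Translation factors were higher for 27 of 28 genes (median 1.71, adjusted p = 4.66e-27) and RNA-binding proteins tied to vesicle loading for 16 of 21, with 2 lower (median 0.88, adjusted p = 4.65e-09). NCL stood at 5.27 ± 0.06 and AGO1 at 3.82 ± 0.07.

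Of the 79 ribosomal protein genes 76 were higher and 1 lower (median 1.67, adjusted p = 1.32e-32, adjusted p = 0.164 with an estimated correlation). Cell cycle genes were higher for 28 of 30 (median 1.201, adjusted p = 1.7e-05, adjusted p = 0.386 with an estimated correlation). Mitochondrially encoded genes were lower for 27 of 29 (median −6.17, or −4.36 with genes at 0 set to their bounds, adjusted p = 1.52e-11, adjusted p = 0.0672 with an estimated correlation). Nuclear-retained long noncoding RNAs were lower for 7 of 9 (adjusted p = 2.75e-05, adjusted p = 0.0516 with an estimated correlation), with MALAT1 at −3.49 ± 0.09. The sphingolipid list was lower for 20 of 37 genes and higher for 8 (median −0.72, adjusted p = 0.0483, adjusted p = 0.164 with an estimated correlation).

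Between GW4869 EVs and cells 13639 of 19495 genes differed, 6472 higher and 7167 lower. Another 8 lists passed with adjusted p of 0.0672 to 0.604 with an estimated correlation. Of these, p53 targets (median 0.62) turned to −0.11 under total count scaling, which ended their call and those of the integrated stress response and of small nucleolar and Cajal body RNAs. The integrated stress response also lost its call with RLE scaling, with a replicate block, without abundant noncoding RNA and histone genes, and without GW4869 cell replicate 1 or 3 or GW4869 EV replicate 2 (medians 0.77, 0.75 and 0.78). Of 30 lists 15 passed camera, and translation factors and RNA-binding proteins held with an estimated correlation. Total count scaling gave 3402 genes higher and 10705 lower, and a mean of at least 10 CPM gave 8210 genes.

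In FTY720 EVs the same mRNAs were enriched over FTY720 cells, but by less than in the other EVs, and a histone mRNA was among the 5 largest rises. RAB13 was 37.1-fold higher than in cells (log2 fold change 5.21 ± 0.14 SE, n = 3 per group), at 27.7 ± 1.40 CPM against 0.741. NET1 was 21.7-fold higher, KIF1C 18.9-fold and TRAK2 17.8-fold. The histone gene H3C7 was 18.9-fold higher (4.24 ± 0.16), and of 58 replication-dependent histones 56 were higher and 0 lower (median 3.14, adjusted p = 4.26e-37, adjusted p = 0.0535 with an estimated correlation). All 30 cell cycle genes were higher, with CDC20, an activator of the anaphase-promoting complex, at 3.19 ± 0.13 (median 2.23, adjusted p = 3.17e-24, adjusted p = 0.0644 with an estimated correlation).

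All 29 mitochondrially encoded genes were lower in FTY720 EVs (median −5.20, or −4.56 at bounds, adjusted p = 4.06e-14), with MT-ATP8 68.5-fold and MT-ND6 63.4-fold lower. The host transcript MIR181A1HG, LINC01355 and the secreted neurexophilin NXPH1 were 72.2-, 70.1- and 64.1-fold lower. Nuclear-retained long noncoding RNAs were lower for 6 of 9 and higher for 2, or 3 adjusted over the list alone (median −3.39, adjusted p = 1.13e-08), with MALAT1 at −4.65 ± 0.10. YAP and TEAD targets were lower for 9 of 13 and higher for 1 (adjusted p = 3.88e-05), with the matricellular CCN2 at −4.93 ± 0.32 and the growth factor TGFB2 at −3.76 ± 0.13. Translation factors were higher for 27 of 28 (median 1.30, adjusted p = 1.22e-20). Vesicle formation and release machinery was higher for 27 of 42 genes and lower for 7, or 28 and 8 adjusted over the list alone (median 0.55, adjusted p = 0.00287, adjusted p = 0.122 with an estimated correlation). Aryl hydrocarbon receptor targets passed at an adjusted p of 0.0274, with adjusted p = 0.146 with an estimated correlation, but not without FTY720 cell replicate 3 (median 2.18). The other 10 lists that passed and did not hold, cytosolic ribosomal proteins (median 1.22) and the integrated stress response (median 1.62) among them, had adjusted p of 0.0741 to 0.274 with an estimated correlation.

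Between FTY720 EVs and cells 13388 of 19495 genes differed, 6349 higher and 7039 lower. Of 30 lists 19 passed camera, and 5 held with an estimated correlation: mitochondrially encoded genes, translation factors, nuclear-retained long noncoding RNAs, RNA-binding proteins tied to vesicle loading, and YAP and TEAD targets. Total count scaling gave 4817 genes higher and 8520 lower, factors from coding genes gave 4562 and 8826, and a mean of at least 10 CPM gave 8220 genes.

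GW4869 cells were compared with DMSO cells to see what the inhibitor changes in the source of the EVs. LIMCH1, which activates nonmuscle myosin II, rose from 3.81 ± 0.42 to 37.6 ± 2.36 CPM (SD, n = 3), a log2 fold change of 3.30 ± 0.14 (SE, adjusted p = 2.15e-09). The phosphodiesterase PDE10A rose 6.77-fold, the transcription factor NFIA 6.65-fold, the guanylate cyclase subunit GUCY1A2 6.40-fold, the laminin chain LAMB1 5.97-fold, ZNF608 5.38-fold, the keratin KRT17 5.36-fold and ANKRD1 5.15-fold. The hormone STC1 fell from 93.2 ± 1.27 to 27.0 ± 3.48 CPM (log2 fold change −1.79 ± 0.10), and OSGIN1, a target of NRF2, by 1.59 ± 0.23 on the log2 scale. LINC01016, the proteoglycan SPOCK1, nestin (NES), CYRIA and LINC00504 fell 2.6-, 2.53-, 2.42-, 2.37- and 2.34-fold. PLAT, which codes for tissue plasminogen activator, was also among the 8 largest falls (−1.23 ± 0.35, adjusted p = 0.0402), but lost its call in 8 alternatives, among them the fits without DMSO replicate 1, 2 or 3 or GW4869 replicate 3 (−0.996 to −1.295).

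Sterol genes moved in opposite directions by function. Of 22 genes of cholesterol synthesis and uptake 20 fell (median −0.47, adjusted p = 1.32e-14, adjusted p = 0.258 with an estimated correlation), with INSIG1, a sterol sensor, at −0.75 ± 0.08 and the LDL receptor LDLR at −0.72 ± 0.09. Of 8 cholesterol efflux genes 4 rose, with the lipid exporters ABCA1 at 1.53 ± 0.09 and ABCG1 at 1.14 ± 0.08 (median 0.42, adjusted p = 1.58e-07, adjusted p = 0.137 with an estimated correlation). Replication-dependent histones fell for 45 of 58 genes, or 51 adjusted over the list alone (median −0.56, adjusted p = 1.85e-23, adjusted p = 0.461 with an estimated correlation). Cell cycle genes fell for 17 of 30, or 20 adjusted over the list alone, with the transcription factor E2F1 at −0.88 ± 0.13 (adjusted p = 5.05e-13, adjusted p = 0.461 with an estimated correlation). Luminal epithelial genes fell for 10 of 14, or 11 adjusted over the list alone, with the mucin MUC1 at −0.77 ± 0.10 and keratin KRT19 at −0.64 ± 0.08 (adjusted p = 1.58e-08, adjusted p = 0.378 with an estimated correlation). Interferon-stimulated genes rose for 10 of 24, or 13 adjusted over the list alone, with IFI27 at 1.25 ± 0.27 (adjusted p = 1.83e-05, adjusted p = 0.518 with an estimated correlation).

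The other 8 lists that passed had medians between −0.34 and 0.07 and adjusted p from 0.378 to 0.773 with an estimated correlation. Of these, estrogen receptor targets (median −0.28) and p53 targets (median 0.07) did not pass without GW4869 replicate 3 (−0.28 and 0.05). Among them, fatty acid synthesis fell for 5 of 14 genes, or 7 adjusted over the list alone, with the desaturases FADS1 at −0.90 ± 0.10 and SCD at −0.56 ± 0.09 (adjusted p = 0.000434, adjusted p = 0.461 with an estimated correlation). Sphingolipid metabolism did not pass, with 4 of 37 genes higher and 5 lower, or 7 and 7 adjusted over the list alone (adjusted p = 0.7). Vesicle formation and release machinery did not pass either (2 of 42 higher, 8 lower, adjusted p = 0.0765).

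GW4869 changed 3455 of 18922 genes in cells, 1796 higher and 1659 lower, and 497 and 104 of these by at least 2-fold. Of 30 lists 14 passed camera and 0 held with an estimated correlation, while fry called 9. The count of genes was 1897, 1886 and 2303 without DMSO replicate 1, 2 or 3, 2034 and 2074 without GW4869 replicate 1 or 3, 1410 with all 18 libraries in the fit, 5634 with only the 6 libraries compared and 6478 in limma-voom.

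FTY720 changed 6075 genes in cells, against 3455 for GW4869. Lipocalin 2 (LCN2), an iron-siderophore binding protein, rose from 0.0597 to 5.51 ± 3.14 CPM (SD, n = 3), a log2 fold change of 6.42 ± 0.77 (SE, adjusted p = 0.000167). The retinol transporter STRA6 rose 38.3-fold, the secretory cell transcription factor BHLHA15 33.9-fold, the tight junction protein CLDN1 21.6-fold (7.04 ± 0.32 against 0.327 CPM), the cytochrome CYP1A1 15.4-fold and CCDC33 13.5-fold. The mitochondrial rRNA MT-RNR2 rose 13.3-fold, at 21.1 ± 17.9 CPM against 1.57, and MT-RNR1 rose 12.2-fold but lost its call without DMSO replicate 1 (3.36). Libraries were depleted of ribosomal RNA, so uneven depletion cannot be told apart from a change in these 2 RNAs. The steroid glucuronidating enzyme UGT2B15 fell by 4.98-fold and the semaphorin receptor PLXNA4 by 3.15-fold (−1.66 ± 0.09, adjusted p = 2.2e-08). PKHD1L1, BRINP3, the cadherins CDH4 and PCDH10, the receptor GPR139 and LINC01016 fell by 4.16-, 4.13-, 3.54-, 3.17-, 3.47- and 3.17-fold.

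All 30 cell cycle genes fell (median −0.94, adjusted p = 1.01e-31, adjusted p = 0.133 with an estimated correlation), with thymidylate synthase (TYMS) at −1.21 ± 0.09 and the proliferation marker MKI67 at −1.17 ± 0.12. Replication-dependent histones fell for 49 of 58, or 52 adjusted over the list alone (median −0.70, adjusted p = 6.03e-27, adjusted p = 0.167 with an estimated correlation). Luminal epithelial genes fell for 9 of 14, or 10 with 1 rise adjusted over the list alone, with the estrogen receptor ESR1 at −0.81 ± 0.14 (adjusted p = 0.0011, adjusted p = 0.337 with an estimated correlation). Estrogen receptor targets fell for 11 of 25 and rose for 2, or 12 and 3 adjusted over the list alone (median −0.20, adjusted p = 0.00146, adjusted p = 0.279 with an estimated correlation).

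Fatty acid synthesis rose for 11 of 14 genes, with SCD at 1.74 ± 0.09 and LPIN1 at 1.48 ± 0.12 (median 0.76, adjusted p = 1.23e-13, adjusted p = 0.0835 with an estimated correlation). Cholesterol synthesis and uptake rose for 16 of 22 and fell for 1, or 2 adjusted over the list alone, with the sterol carrier STARD4 at 1.33 ± 0.13 (median 0.48, adjusted p = 8.07e-08, adjusted p = 0.167 with an estimated correlation). Cholesterol efflux rose as well, for 5 of 8, with ABCA1 at 2.29 ± 0.09 and ABCG1 at 1.69 ± 0.08 (adjusted p = 1.97e-10, adjusted p = 0.0555 with an estimated correlation). Lysosome and autophagy genes rose for 18 of 32 and fell for 4, or 21 and 4 adjusted over the list alone, with GPNMB at 2.18 ± 0.21 and the autophagy receptor SQSTM1 at 1.25 ± 0.10 (adjusted p = 3.48e-09, adjusted p = 0.133 with an estimated correlation).

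All 8 inflammatory genes rose, with the NF-kB regulator TNFAIP3 at 3.12 ± 0.20 (median 1.69, adjusted p = 2.26e-13, adjusted p = 0.0835 with an estimated correlation). Interferon-stimulated genes rose for 19 of 24, or 23 with 1 fall adjusted over the list alone, with the RNA sensors OAS1 at 3.06 ± 0.22 and DDX60 at 3.04 ± 0.37 (median 1.07, adjusted p = 5.69e-12, adjusted p = 0.167 with an estimated correlation). Immediate early genes rose for 18 of 20, or 19 adjusted over the list alone, with ATF3 at 1.69 ± 0.15 (adjusted p = 1.66e-14, adjusted p = 0.163 with an estimated correlation). Of 18 endoplasmic reticulum chaperones 15 rose, or 16 adjusted over the list alone, with DNAJB9 at 1.94 ± 0.23 and HSPA5 at 1.10 ± 0.19 (adjusted p = 3.56e-07, adjusted p = 0.276 with an estimated correlation). The integrated stress response rose for 15 of 22 and fell for 3, with the transcription factor DDIT3 at 2.42 ± 0.22 (median 0.58, adjusted p = 1.21e-05, adjusted p = 0.337 with an estimated correlation). p53 targets rose for 11 of 18, with 1 fall adjusted over the list alone, and the inhibitor CDKN1A at 1.05 ± 0.10 (adjusted p = 0.000128, adjusted p = 0.158 with an estimated correlation). Hypoxia and glycolysis genes rose for 10 of 17 and fell for 2, or 11 and 2 adjusted over the list alone, with VEGFA at 1.31 ± 0.15 (adjusted p = 0.000219, adjusted p = 0.133 with an estimated correlation). The heat shock response did not pass, with 1 of 12 genes higher and 1 lower (median 0.08, adjusted p = 0.639).

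FTY720 changed 6075 of 18922 genes in cells, 3098 higher and 2977 lower, 925 and 432 of these by at least 2-fold. Another 6 lists that passed had medians of −0.12 to 0.42 and adjusted p of 0.0722 to 0.655 with an estimated correlation. Of these, nuclear-encoded respiratory chain subunits lost the call without FTY720 replicate 1 (−0.096), and nuclear-retained long noncoding RNAs without DMSO replicate 1 (0.16) or FTY720 replicate 1 (0.033). Of 30 lists 21 passed camera and 0 held with an estimated correlation. With all 18 libraries in the fit, 3064 genes were called.

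Set against each other in cells, at 5 and 10 µM, the drugs differed in lipid synthesis, inflammatory and lysosome genes. Of 22 genes of cholesterol synthesis and uptake 19 were higher under FTY720 and 0 lower, or 20 adjusted over the list alone, with STARD4 at 1.80 ± 0.14, INSIG1 at 1.66 ± 0.08 and LDLR at 1.30 ± 0.09 (SE, n = 3 per group, median 0.97, adjusted p = 1.44e-44). Fatty acid synthesis was higher for 13 of 14 genes, with SCD at 2.31 ± 0.10 (median 0.99, adjusted p = 2.37e-36). All 8 inflammatory genes were higher (median 1.45, adjusted p = 3.38e-15), and lysosome and autophagy genes for 22 of 32, with 1 lower, or 2 adjusted over the list alone (adjusted p = 2.55e-15). The integrated stress response was higher for 18 of 22, with the cystine transporter SLC7A11 at 3.27 ± 0.46 (adjusted p = 2.05e-19, adjusted p = 0.079 with an estimated correlation), and all 18 endoplasmic reticulum chaperones were higher (adjusted p = 4.93e-18, adjusted p = 0.079 with an estimated correlation). Cell cycle genes were lower under FTY720 for 25 of 30, or 27 adjusted over the list alone (median −0.58, adjusted p = 1.39e-13, adjusted p = 0.257 with an estimated correlation).

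LCN2, BHLHA15, STRA6, CYP1A1 and CCDC33 were 28.1-, 26.0-, 23.6-, 16.2- and 15.2-fold higher under FTY720, and STRA6 lost its call in limma-voom. UGT2B15, ZPLD1, the actin-binding SYNPO2, the calcium channel CACNA1C and the receptor HTR1F were 5.06-, 4.13-, 3.73-, 3.66- and 3.46-fold lower, and HTR1F lost its call with no filter on low counts. The drugs differed at 4180 of 18922 genes in cells, 2083 higher and 2097 lower under FTY720, and at 1840 with all 18 libraries in the fit. Without GW4869 replicate 3, 1303 were lower. Of 30 lists 20 passed camera, 10 of them besides those given, with adjusted p of 0.0742 to 0.618 with an estimated correlation. Among these, p53 targets (median 0.02, −0.01 under total count scaling) lost the call without GW4869 replicate 2 (−0.0057), nuclear-retained long noncoding RNAs without FTY720 replicate 1 or 2 (0.15 and 0.16), and vesicle formation and release machinery without GW4869 replicate 1 (0.059) or FTY720 replicate 2 or 3 (0.073 and 0.049) and under total count scaling. The 7 that held with an estimated correlation were cholesterol synthesis and uptake, fatty acid synthesis, lysosome and autophagy, inflammatory, hypoxia and glycolysis, aryl hydrocarbon receptor targets, and YAP and TEAD targets.

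Cell responses to the drugs also shared genes: 1059 rose and 1049 fell under both, against 294 and 261 under independence. Another 103 were called in opposite directions. In EVs 162 rose and 179 fell under both, against 92.5 and 120 under independence, with 379 in opposite directions. In 20 simulations at most 0 rose and 1 fell under both in cells, and 1 and 0 in EVs. Having unchanged groups, they cannot show what shared controls add among changed genes. The covariance of log2 fold changes exceeded its simulated value in cells (0.159 against 0.0203) but not in EVs (0.0749 against 0.0851). At a 2-fold threshold 301 rose and 40 fell under both in cells, and 10 and 24 in EVs.

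In EVs under GW4869, 112 genes fell and 39 rose by at least 2-fold, and mitochondrial, histone, luminal and integrated stress response transcripts were lower as lists. LIMCH1 rose in EVs as in cells, from 2.48 ± 0.53 to 12.5 ± 3.04 CPM (SD, n = 3), a log2 fold change of 2.34 ± 0.26 (SE, adjusted p = 8.25e-05), and PDE10A rose 2.45-fold. CELSR2, a cadherin of planar polarity, fell from 374 ± 41.9 to 110 ± 11.3 CPM (−1.76 ± 0.09, adjusted p = 2.17e-08). ARC, which forms capsid-like particles, fell by 4.12-fold, and the transcription factor SNAI1 by 4.23-fold. MT-ND2 and MT-ND5, subunits of complex I, fell by 4.41- and 2.89-fold. MT-ND1 fell by 4.66-fold and MT-CO2, a subunit of cytochrome oxidase, by 3.11-fold, and both lost their call with no filter on low counts. MT-ND4L (−1.73 ± 0.40) lost its call without DMSO EV replicate 2 or 3 or GW4869 EV replicate 1 (−1.59 to −1.70), and the synaptotagmin SYT17 (1.25 ± 0.26) without DMSO EV replicate 2 (1.18). The other 5 of the 8 largest rises, MIR3150BHG, NFIA, PARVB, NINJ2-AS1 and LINC01504 (2.66-, 2.58-, 2.51-, 2.38- and 2.30-fold), each lost their call without DMSO EV replicate 2 or 3 (0.98 to 1.57 on the log2 scale). MIR3150BHG did so without DMSO EV replicate 1 (1.41) or GW4869 EV replicate 1 (1.196) as well, NFIA without GW4869 EV replicate 1 (1.06), and PARVB and NINJ2-AS1 without GW4869 EV replicate 2 (1.21 and 1.13). LINC01504 lost its call without any 1 library except GW4869 EV replicate 1 (1.01 to 1.41).

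Replication-dependent histones fell in GW4869 EVs for 43 of 58 genes, or 48 adjusted over the list alone, with H4C6 at −1.44 ± 0.16 (SE, n = 3 per group, median −0.76, adjusted p = 7.69e-62). Mitochondrially encoded genes fell for 10 of 15, or 11 adjusted over the list alone (median −1.51, adjusted p = 1.34e-25). Luminal epithelial genes fell for 6 of 14, or 7 adjusted over the list alone, with E-cadherin (CDH1) at −1.22 ± 0.06 (adjusted p = 8.99e-12). Of 18 endoplasmic reticulum chaperones 7 fell, with HSPA5 at −1.23 ± 0.09, or 9 with 2 rises adjusted over the list alone (adjusted p = 2.29e-10). Cholesterol synthesis and uptake fell for 6 of 22, or 8 adjusted over the list alone, with LDLR at −0.89 ± 0.07 and DHCR7 at −0.85 ± 0.08 (median −0.24, adjusted p = 2.41e-09). Estrogen receptor targets fell for 8 of 25, or 10 with 1 rise adjusted over the list alone (adjusted p = 5.23e-09). The integrated stress response fell for 6 of 22, or 7 with 2 rises adjusted over the list alone, with the amino acid transporters SLC7A5 at −1.27 ± 0.16 and SLC3A2 at −1.09 ± 0.12 (adjusted p = 6.45e-07). Sphingolipid metabolism fell for 4 of 36, or 5 adjusted over the list alone (median −0.18, adjusted p = 0.0157, adjusted p = 0.0649 with an estimated correlation). Vesicle formation and release machinery did not pass, with 2 of 42 higher and 4 lower (median 0.01, mean and test below 0, adjusted p = 0.735).

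GW4869 changed 1083 of 16419 genes in EVs, 449 higher and 634 lower, and 39 and 112 of these by at least 2-fold. Of 29 lists 19 passed camera, and 7 held with an estimated correlation: histones, mitochondrially encoded, luminal epithelial and endoplasmic reticulum chaperone genes, cholesterol synthesis and uptake, estrogen receptor targets and the integrated stress response. The other 11 had adjusted p of 0.0633 to 0.695 with an estimated correlation. Of these, cytosolic ribosomal proteins lost the call without DMSO EV replicate 2 or GW4869 EV replicate 2 (medians −0.053 and −0.086), translation factors without DMSO EV replicate 1 or GW4869 EV replicate 1 (0.005 and 0.011), and small noncoding RNAs without DMSO EV replicate 2 or GW4869 EV replicate 1 (−0.70 and −0.66). Hypoxia and glycolysis genes lost it without DMSO EV replicate 3 (−0.13) or GW4869 EV replicate 1 or 2 (−0.097 and −0.22). Without DMSO EV replicate 1, 297 genes were higher. The count of genes was 538 and 563 without DMSO EV replicate 2 or 3, 520 with only the 6 libraries compared and 2503 with all 18 libraries in the fit.

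FTY720 changed EV RNA widely: messages of the integrated stress response and of lipid synthesis rose, and many RNAs enriched in EVs fell. The stress-induced NIBAN1 rose from 4.57 ± 0.47 to 70.9 ± 1.41 CPM (SD, n = 3), a log2 fold change of 3.95 ± 0.15 (SE, adjusted p = 2.8e-12). PTPN23, a phosphatase of the endosomal sorting (ESCRT) pathway, rose from 24.2 ± 4.20 to 269 ± 8.72 CPM (3.47 ± 0.13). BHLHA15 rose 29.2-fold, the mitochondrial folate enzyme ALDH1L2 14.8-fold, the cytokine receptor IL21R 11.3-fold, DDIT3 10.8-fold and the chaperone DNAJB9 10.2-fold. PRUNE2 (3.78 ± 1.06) lost its call without FTY720 EV replicate 1, 2 or 3 (3.70 to 3.84), in DESeq2 and with no filter. C1orf115 fell from 444 ± 12.8 to 17.9 ± 1.05 CPM (−4.63 ± 0.07, adjusted p = 9.16e-17), WDR87 by 29.7-fold and the potassium channel KCND1 by 22.5-fold. SPACA6, LINC01166, LINC01409 and the antisense transcripts SYNGAP1-AS1 and SRP14-AS1 fell by 21.6-, 29.1-, 24.1-, 27.6- and 22.7-fold. Of 326 genes at least 8-fold higher in DMSO EVs than in cells, 305 fell under FTY720 and 8 rose, with a median of −2.96. Under GW4869 8 fell and 58 rose, with a median of 0.103.

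Cholesterol synthesis and uptake rose in FTY720 EVs for 19 of 22 genes and fell for 1, with STARD4 at 2.85 ± 0.19 and HMGCS1, the synthase of HMG-CoA, at 2.42 ± 0.09 (SE, n = 3 per group, median 1.48, adjusted p = 7.09e-16). The integrated stress response rose for 18 of 22 and fell for 1, or 19 and 1 adjusted over the list alone, with SLC7A11 at 3.16 ± 0.20 and TRIB3 at 2.35 ± 0.07 (median 1.61, adjusted p = 1e-15). Fatty acid synthesis rose for 13 of 14, with fatty acid synthase (FASN) at 2.07 ± 0.08 and SCD at 1.88 ± 0.05 (median 1.51, adjusted p = 1.1e-12). Replication-dependent histones rose for 55 of 58, with H2BC11 at 2.04 ± 0.11 (median 1.55, adjusted p = 1.37e-26, adjusted p = 0.129 with an estimated correlation). Of 18 endoplasmic reticulum chaperones 14 rose and 2 fell (median 0.84, adjusted p = 0.000302, adjusted p = 0.13 with an estimated correlation). Immediate early genes rose for 13 of 20 (adjusted p = 0.000188, adjusted p = 0.0593 with an estimated correlation), and oxidative stress genes for 10 of 14 (adjusted p = 0.00074, adjusted p = 0.0735 with an estimated correlation). Lysosome and autophagy genes rose for 12 of 32 and fell for 2 (median 0.18, adjusted p = 0.0101, adjusted p = 0.129 with an estimated correlation). Cell cycle genes rose for 21 of 30 and fell for 2, or 23 and 3 adjusted over the list alone (median 0.45, adjusted p = 0.00188, adjusted p = 0.277 with an estimated correlation).

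RNA-binding proteins tied to vesicle loading rose for 6 of 20 genes and fell for 8 (adjusted p = 0.0292, adjusted p = 0.199 with an estimated correlation), and their median of −0.07 turned to 0.33 under total count scaling, which also ended the call. AGO1 fell by 3.20 on the log2 scale (SE 0.05) and NCL by 2.60 (SE 0.04). Ribosomal protein genes fell for 47 of 78 and rose for 3, or 52 and 3 adjusted over the list alone (adjusted p = 0.0329, adjusted p = 0.833 with an estimated correlation). Their median of −0.26 turned to 0.14 under total count scaling, and the call was lost there, without DMSO EV replicate 2 (−0.21) and without FTY720 EV replicate 1 (−0.16). Translation factors did not pass (6 of 28 higher, 10 lower, adjusted p = 0.156), with EIF3A at −2.57 ± 0.05. Mitochondrially encoded genes did not pass as a list, though 10 of 15 fell (adjusted p = 0.0683), and the heat shock response did not pass, with 6 of 12 lower and 0 higher, or 6 and 1 adjusted over the list alone (median −0.29, adjusted p = 0.192). Neither did vesicle formation and release machinery (18 of 42 higher, 6 lower, or 18 and 7 adjusted over the list alone, adjusted p = 0.156) nor sphingolipid metabolism (8 of 36 higher, 6 lower, or 9 and 6 adjusted over the list alone, median 0.12, mean −0.06, adjusted p = 0.972).

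FTY720 changed 6496 of 16419 genes in EVs, 3384 higher and 3112 lower, and 670 and 1738 of these by at least 2-fold. Of 29 lists 12 passed camera, and cholesterol synthesis and uptake, integrated stress response and fatty acid synthesis held with an estimated correlation. Total count scaling moved the median of all genes to 0.378 and gave 6389 genes higher and 1892 lower, and it also ended the call of inflammatory genes (median 1.14, adjusted p = 0.0273, adjusted p = 0.277 with an estimated correlation).

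**Figure D3:**
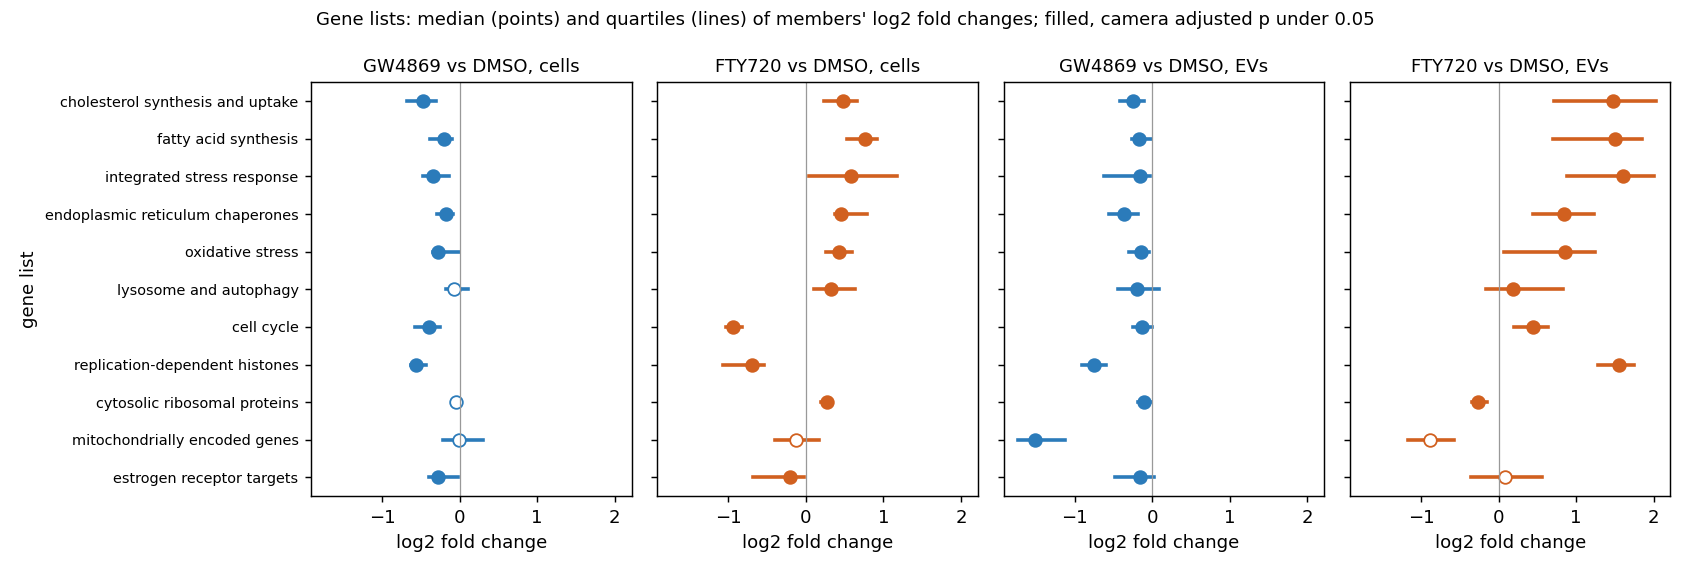
Median (points) and quartiles (lines) of the log2 fold changes of 11 gene lists under each drug against DMSO, in cells and in EVs, filled where camera passed at an adjusted p under 0.05. Cholesterol synthesis and uptake lies below 0 under GW4869 (−0.47 in cells, −0.24 in EVs) and above 0 under FTY720 (0.48 and 1.48); ribosomal proteins in FTY720 EVs (−0.26) turn to 0.14 under total count scaling.

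Compared directly in EVs, at 5 and 10 µM, FTY720 stood above GW4869 in RNAs of the integrated stress response and of lipid synthesis. BHLHA15 was 71.5-fold higher, SLC7A11 32.7-fold (5.03 ± 0.23 SE, n = 3 per group, adjusted p = 3.52e-11), the glutathione-degrading CHAC1 22.6-fold, ALDH1L2 18.9-fold and the amino acid transporter SLC1A4 17.4-fold. C1orf115 was 33.9-fold lower, and STON1-GTF2A1L, WDR87, SYNGAP1-AS1 and SRP14-AS1 were 31.3-, 29.8-, 28.5- and 28.3-fold lower. Histones were higher for 56 of 58 genes and lower for 0 (median 2.40, adjusted p = 2.22e-46), cholesterol synthesis and uptake for 20 of 22 (median 2.01, adjusted p = 1.22e-20), and fatty acid synthesis for 13 of 14 (median 1.65, adjusted p = 8.29e-14). The integrated stress response was higher for 19 of 22 and lower for 1, or 20 and 1 adjusted over the list alone (median 1.63, adjusted p = 5.76e-19). Of 18 endoplasmic reticulum chaperones 17 were higher and 1 lower, with HERPUD1 at 3.01 ± 0.13 and HSPA5 at 2.05 ± 0.09 (adjusted p = 1.29e-07). The heat shock response did not pass, with 1 of 12 genes higher and 6 lower (median −0.21, adjusted p = 0.295).

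The drugs differed at 7035 of 16419 genes in EVs, 3707 higher and 3328 lower under FTY720. Of 29 lists 14 passed camera, and 8 held with an estimated correlation: histones, cholesterol synthesis and uptake, fatty acid synthesis, integrated stress response, endoplasmic reticulum chaperones, immediate early genes, oxidative stress, and lysosome and autophagy. The other 6 had adjusted p of 0.0846 to 0.294 with an estimated correlation, and 2 of them turned and lost the call under total count scaling: translation factors (median −0.15, 0.26 there) and RNA-binding proteins tied to vesicle loading (−0.03, 0.38 there). Translation factors also lost the call without GW4869 EV replicate 1 or 3 or FTY720 EV replicate 1 (−0.12, −0.13 and −0.097). Total count scaling gave 6753 genes higher and 1993 lower.

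The next comparison asked whether a drug changed EVs differently from the cells that release them. For FTY720 it did so at 6195 of 19495 genes, with 3236 effects higher in EVs and 2959 lower. PTPN23 rose in EVs by 3.37 ± 0.18 on the log2 scale more than in cells (SE, n = 3 per group, adjusted p = 1.91e-12), and RAB13 was 35.6-fold lower relative to its change in cells (−5.15 ± 0.28). Replication-dependent histones went opposite ways: the difference was above 0 for 55 of 58 genes, or 56 adjusted over the list alone (median 2.41, adjusted p = 8.88e-49, adjusted p = 0.0761 with an estimated correlation). Cell cycle genes differed the same way for 28 of 30 (median 1.45, adjusted p = 5.41e-20, adjusted p = 0.236 with an estimated correlation). Cholesterol synthesis and uptake rose more in EVs for 17 of 22, with 1 lower adjusted over the list alone (median 1.26, adjusted p = 1.42e-08, adjusted p = 0.0761 with an estimated correlation). Ribosomal proteins were lower in EVs relative to cells for 59 of 79 and higher for 1, or 63 and 2 adjusted over the list alone (median −0.50, adjusted p = 2.66e-06, adjusted p = 0.737 with an estimated correlation). Total count scaling gave 6215 effects higher and 1946 lower in EVs, and factors from coding genes gave 1976 and 3929.

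**Figure D4:**
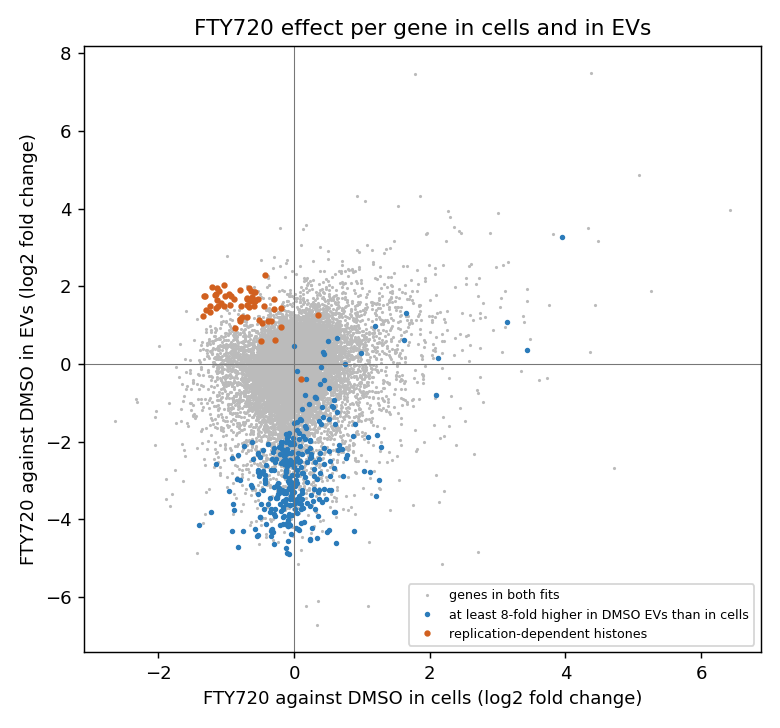
FTY720 against DMSO as log2 fold change per gene, in cells (horizontal axis) and in EVs (vertical axis). Genes at least 8-fold higher in DMSO EVs than in cells (blue, median −2.96 in EVs) lie mostly below 0 in EVs, and replication-dependent histones (orange, medians −0.70 in cells and 1.55 in EVs) lie mostly in the upper left.

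For GW4869 the effect differed between EVs and cells at 869 of 19495 genes, 276 higher and 593 lower in EVs. The receptor kinase GRK5 had a difference of 1.76 ± 0.38 (SE, n = 3 per group, adjusted p = 0.0118). ABCA1, which rose in cells, had a difference of −1.78 ± 0.26. Cholesterol efflux had 2 of 8 genes lower (median −0.42, adjusted p = 0.00599, adjusted p = 0.0912 with an estimated correlation), and mitochondrially encoded genes 10 of 29, or 15 adjusted over the list alone (median −1.44, or −1.09 at bounds, adjusted p = 8.46e-13, adjusted p = 0.0912 with an estimated correlation). The kinase TSSK3 had 0 counts in GW4869 EVs and was at least 10.2-fold lower there than in DMSO EVs. Of 30 lists 14 passed camera and 0 held with an estimated correlation, and for FTY720 9 passed and 0 held. The count of genes for GW4869 was 351, 369 and 452 without DMSO cell replicate 1, 2 or 3, 390 and 467 without GW4869 cell replicate 1 or 3, and 1378 and 1761 without GW4869 EV replicate 1 or 2. The count of effects higher in EVs (276) ran from 71 without GW4869 cell replicate 1 to 541 without GW4869 EV replicate 2, and was 183 without GW4869 cell replicate 2 and 432 without GW4869 EV replicate 3. The count of genes in both directions was 1730 in DESeq2 and 433 in limma-voom. Scaling by total counts, by RLE and by coding genes gave 179, 201 and 190 effects higher in EVs and 709, 731 and 737 lower.

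Across genes, log2 fold changes in EVs and in cells correlated weakly for both drugs, and genes are not independent replicates. For GW4869 Pearson's r was 0.196 and Spearman's rho 0.259 over 15807 genes, and r was 0.422 for genes with at least 5 CPM in both. Without GW4869 EV replicate 2 it was 0.0952. Of 433 genes called in both compartments 410 changed in the same direction, where independence gives 212 called in both. For FTY720 r was 0.178 and rho 0.167, and of 2497 genes called in both 1637 changed in the same direction and 860 in opposite directions.

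Enzymes and receptors that the drugs act on were followed in every comparison. SMPD3, which codes for neutral sphingomyelinase 2, rose in GW4869 cells by 0.91 ± 0.23 (SE, n = 3 per group, adjusted p = 0.0134), but not past the threshold with all 18 libraries or without DMSO cell replicate 2 or 3 (0.80 in both). It stood lower in EVs than in cells under DMSO (−1.47 ± 0.57, adjusted p = 0.0277), a call lost without DMSO cell replicate 1 (−1.24), without DMSO EV replicate 1 (−0.87) and with only the 6 libraries compared. SMPD4 (chromosome 2, 130151392 to 130182750), another neutral sphingomyelinase, rose in FTY720 EVs by 0.54 ± 0.11 (adjusted p = 0.000836). It was higher in FTY720 than in GW4869 EVs by 0.94 ± 0.11 (adjusted p = 3.19e-06), and its FTY720 effect differed between EVs and cells by 0.80 ± 0.14 (adjusted p = 0.000125). In GW4869 EVs SMPD4 was lower at −0.41 ± 0.11 (adjusted p = 0.0387), a call lost without DMSO EV replicate 1 (−0.39), 2 (−0.45) or 3 (−0.39), without GW4869 EV replicate 1 (−0.32) or 2 (−0.37), and with only the 6 libraries compared. In FTY720 cells it was lower at −0.24 ± 0.08 (adjusted p = 0.0277), lost with all 18 libraries, with only the 6 compared, and without DMSO cell replicate 1, 2 or 3 or FTY720 cell replicate 1 or 2 (−0.25 to −0.20).

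S1PR3, a sphingosine 1-phosphate receptor, rose in FTY720 cells by 0.84 ± 0.13 (SE, n = 3 per group, adjusted p = 0.000135) and was higher in EVs than in cells under DMSO by 1.22 ± 0.22 (adjusted p = 4.46e-05). In GW4869 EVs S1PR3 stood at −0.98 ± 0.25 (adjusted p = 0.0311), a call lost without DMSO EV replicate 2 (−0.84) or 3 (−1.002), without GW4869 EV replicate 2 (−0.84) or 3 (−0.76), and with only the 6 libraries compared. The sphingosine kinase SPHK1 was higher in EVs than in cells under DMSO (1.64 ± 0.27), GW4869 (1.45) and FTY720 (1.21), and higher in FTY720 than in GW4869 cells (0.69, adjusted p = 0.0116), a call lost with all 18 libraries. SMPD1, which codes for acid sphingomyelinase, did not pass in any drug comparison against DMSO: it stood at 0.07 (adjusted p = 0.818) and 0.24 (adjusted p = 0.291) in GW4869 and FTY720 cells and at −0.24 (adjusted p = 0.823) and 0.24 (adjusted p = 0.711) in GW4869 and FTY720 EVs. S1PR1, S1PR2 and S1PR4 were too low for any fit, with 1, 1 and 3 counts over all 18 libraries.

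Lists of markers of other cell types had fewer than 5 members in the fits and were not tested. Their summed levels, in CPM of total counts without TMM factors, in DMSO cells and in DMSO, GW4869 and FTY720 EVs were 0.213, 1.73, 0.0482 and 0.283 CPM for red cell genes, 2.57, 1.43, 1.09 and 1.37 CPM for platelet genes, and 4.15, 3.34, 1.54 and 1.204 CPM for liver and serum protein genes. Leukocyte genes stood at 1.99, 4.02, 3.75 and 6.23 CPM, fibroblast genes at 22.5, 10.9, 12.6 and 16.0 CPM and endothelial genes at 155, 50.9, 55.1 and 34.6 CPM. Metallothioneins, with too few members in the fits, stood at 44.3, 30.9, 26.3 and 81.9 CPM, and ribosomal RNA genes at 1.61, 0.183, 0.844 and 0.0671 CPM.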

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

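Of the tests here, 2 were chosen after the result was seen: the share of cellular RNA that would explain the fall of EV-enriched RNAs, and detected genes at equal depth in GW4869 EVs.

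EV RNA followed the RNA of the cells in part. Under FTY720, RNAs enriched in EVs such as RAB13 fell, and histone and cholesterol synthesis RNAs rose beyond their change in cells (camera adjusted p = 0.0761 with an estimated correlation for both lists). Under GW4869, 410 of 433 genes called in both EVs and cells changed in the same direction, and r was 0.196 over all genes and 0.422 over genes of at least 5 CPM. Still, 10 of 29 mitochondrially encoded RNAs, or 15 adjusted over the list alone (adjusted p = 0.0912 with an estimated correlation), and the lipid exporter ABCA1 stood lower in EVs relative to their change in cells.

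The difference between the effect in EVs and the effect in cells passed the threshold at 6195 genes for FTY720. The largest differences above 0 were PTPN23 at 3.37, the histones H2AC16 at 3.21, H2BC13 at 3.12, H2BC3 at 3.12 and H2BC11 at 3.10, and the largest below 0 were WDR87 at −6.07, RAB13 at −5.15, MIR4429 at −4.88, SYNGAP1-AS1 at −4.86 and STON1-GTF2A1L at −4.80. SMPD4 passed at 0.80. The lists that differed had medians of 2.41 for replication-dependent histones, 1.45 for cell cycle, 1.26 for cholesterol synthesis and uptake, 0.86 for the integrated stress response, 0.72 for fatty acid synthesis and 0.64 for luminal epithelial genes. All 9 lists, those below 0 included, lost their call with an estimated correlation (adjusted p = 0.0761 to 0.737). Cytosolic ribosomal proteins had −0.50, translation factors −0.29 and RNA-binding proteins tied to vesicle loading −0.0925, and the last 2 turned to 0.09 and 0.28 under total count scaling and lost their calls there (adjusted p = 0.211 and 0.48). Luminal epithelial genes lost their call with RLE scaling and without FTY720 cell replicate 1 (0.58), and RNA-binding proteins without abundant noncoding RNA and histone genes and without DMSO EV replicate 2 or 3 or FTY720 EV replicate 3 (−0.09, −0.12 and −0.11). Of 40 splits of the libraries drawn from 200 possible, the real one included, 1 gave as many genes. The highest other gave 4832, with the real groups of EVs and mixed groups of cells. The splits mix the treatments. They test only for FTY720 acting in at least 1 compartment, not for which, nor for a difference between the effects.

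For GW4869 the difference passed at 869 genes. GHRLOS stood at 2.12, CHSY3 at 1.78, GRK5 at 1.76, SAP30L-AS1 at 1.75 and SMIM15-AS1 at 1.61, and TSSK3, LINC01339, MINAR2, LINC02803 and CD59, at 0 in GW4869 EVs, were at least 10.2-, 2.9-, 2.64-, 1.99- and 1.85-fold lower than in DMSO EVs. CHSY3, GHRLOS and SMIM15-AS1 lost their call without DMSO cell replicate 1, 2 or 3 and without most other libraries (1.17 to 1.97, 1.71 to 2.25 and 1.39 to 1.64). LINC02803 lost it without DMSO cell replicate 1, 2 or 3, GW4869 cell replicate 1 or DMSO EV replicate 2 or 3, CD59 without DMSO cell replicate 2 or DMSO EV replicate 2, and MINAR2 without DMSO EV replicate 3. The lists that differed had medians of −1.44 for mitochondrially encoded genes, −0.42 for cholesterol efflux, −0.94 for spliceosomal and U7 snRNAs, 0.27 for cell cycle, 0.23 for cholesterol synthesis and uptake and 0.13 for translation factors. All 14 lists, with the 8 that follow, lost their call with an estimated correlation (adjusted p = 0.0912 to 0.601), and 6 of them with fry. Another 8 lost their call without 1 or more libraries: small nucleolar and Cajal body RNAs (−0.95), small noncoding RNAs (−0.69), immediate early genes (−0.31), histones (−0.23), sphingolipid metabolism (−0.18), lysosome and autophagy (−0.15), aryl hydrocarbon receptor targets (0.37) and RNA-binding proteins tied to vesicle loading (0.0509, mean below 0). Without GW4869 EV replicate 1 all 8 lost it, with medians in the same order of −1.04, −0.38, −0.12, −0.13, −0.17, −0.18, 0.30 and 0.080, and without DMSO EV replicate 3 all but immediate early genes did (−0.93, −0.60, −0.18, −0.17, −0.13, 0.37 and 0.058). Each other library except DMSO cell replicate 2 ended the call of 1 or more of the 8. RLE scaling ended those of small nucleolar RNAs and RNA-binding proteins, and total count scaling the latter. Of 40 splits drawn from 200 possible 1 gave as many genes, and the highest other, with the real groups of cells and mixed groups of EVs, gave 630. Here too the splits do not test the difference between the effects, and without 1 library the count fell as low as 351 (DMSO cell replicate 1).

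The 9 comparisons of 3 libraries with 3 have 10 splits each, too few for a share under 0.05. In each, 1 split, the real one, gave as many genes, and the highest other gave 0. The real values were 12772, 13639 and 13388 for EVs against cells under DMSO, GW4869 and FTY720, 3455, 6075 and 4180 for the drug comparisons in cells, and 1083, 6496 and 7035 for those in EVs.

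RNAs enriched in EVs fell in FTY720 EVs: of 326 genes at least 8-fold higher in DMSO EVs than in cells, 305 fell (median −2.96, quartiles −3.65 and −2.19). RNA with the make-up of the FTY720 cell libraries, mixed into the EVs, would have to be 92.3% of the RNA to lower them so. Genes enriched in cells allowed −2.1% (quartiles −5.2% and 0.938%), which argues against a mixture with whole-cell RNA. RNA from part of the cell or from a subset of the cells was not tested. Without the most abundant genes the median was −2.97 over 319 genes, and for 358 genes chosen on the GW4869 libraries instead it was −2.8, against a few dominant genes and against a return to the mean. An effect of FTY720 on which RNAs enter EVs, or on which EVs were collected, may explain it and was not tested apart.

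Histone RNAs rose in FTY720 EVs (median 1.55) and fell in FTY720 cells (median −0.70). Sets of genes matched on length and GC content had an upper limit of 0.0156 (the central 95% of 10000 sets), and 57 of 58 histones stood above both DMSO EVs and FTY720 cells, so neither these traits nor mixed-in cellular RNA gives the rise. The summed share of histone counts rose 3.92-fold, which reads shared between histone copies leave unchanged. An action of FTY720 on the EVs released or the cells is a candidate explanation found on the same data and was not tested. A difference in library preparation from DMSO EVs cannot be told apart from it.

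GW4869 EV libraries held fewer genes above 0 counts, but not fewer with at least 10 counts (15129 at equal depth, against 14996 under DMSO and 14689 under FTY720). At equal depth the most genes above 0 in a GW4869 EV library was 19386, below the fewest in an FTY720 EV library (22573) but above the fewest in a DMSO EV library (18969), so depth is not the cause of the gap to FTY720. Of 71 genes at 2 to 5 CPM in the other EVs with 0 counts in a GW4869 EV library, 70 had counts in another of the 3, where Poisson sampling of reads gives 8.4e-16 missing pairs and 78 were seen. Few RNA molecules per low gene may therefore explain the missing genes. RNA input was stated as 2 to 6 ng for the drug-treated EVs and not stated for DMSO EVs.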

How the results depend on the processing

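Tests added after the data were seen are listed above. Of 9042 values of named genes with 1 library left out, 8442 kept direction and side of the threshold, 593 no longer passed, 6 newly passed and 1 turned. Of 15158 under the other settings 14832 did, 298 no longer passed, 23 newly passed and 5 turned. For lists 1092 of 1164 and 827 of 1003 did. Total counts of called genes stayed within 1.5-fold in the settings not named here, and a block for replicate number, which does not pair samples, gave 12524, 13464, 13124, 3394, 5858, 4015, 993, 6359, 6877, 686 and 6030 genes in the order EVs against cells (DMSO, GW4869, FTY720), cells and EVs (GW4869 against DMSO, FTY720 against DMSO, FTY720 against GW4869), and effect differences (GW4869, FTY720).

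The effect difference of GW4869 (869 genes) was 1730 in DESeq2 and 433 in limma-voom. GW4869 in cells (3455) gave 6478 in limma-voom, 1410 with all 18 libraries and 5634 with only the 6 compared. All 18 libraries gave 3064 for FTY720 in cells, 1840 for FTY720 against GW4869 in cells and 2503 for GW4869 in EVs, where only the 6 compared gave 520. The cause was not tested. A mean of at least 10 CPM gave 8056, 8210 and 8220 for EVs against cells under DMSO, GW4869 and FTY720, with fewer genes tested.

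With an estimated correlation camera called 3, 2 and 5 lists for EVs against cells (DMSO, GW4869, FTY720), 0, 0 and 7 in cells, 7, 3 and 8 in EVs, and 0 and 0 for the effect differences. Fry, which does not compare a list with other genes, called 25 and 27 lists for EVs against cells under DMSO and GW4869, 9 for GW4869 in cells, 22 and 24 for FTY720 against DMSO and against GW4869 in EVs, and 8 and 19 for the effect differences. Without abundant noncoding and histone genes 9 lists were called for the GW4869 difference. A 2-fold threshold left 301 genes higher and 40 lower under both drugs in cells and 10 and 24 in EVs. The correlation of cell and EV responses to GW4869 was 0.422 over genes of at least 5 CPM.

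Leaving out 1 library gave 1886 to 3080 genes for GW4869 in cells, 538 to 1195 for GW4869 in EVs and 351 to 1761 for the GW4869 difference, with 6 to 15 lists, and a correlation of 0.0952 to 0.196 for GW4869. Fewer libraries lower the power, but the count rose to 1761 without GW4869 EV replicate 2.

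Directions turned under total count scaling for SMPD4 in EVs against cells under DMSO (−0.51), for ACLY (−0.0856) and SPHK2 (−0.0808) under GW4869, and for TIPARP under FTY720 (−0.0586, and −0.12 with factors from coding genes). S1PR5 in EVs against cells under GW4869 ran from −6.30 without GW4869 EV replicate 1 to 0.88 without replicate 2. Fewer simulated changes were found in EVs: at 1.5-fold, 25.4% of changed genes for GW4869 in EVs and 53.7% in cells.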

Other observations

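Both tests here were chosen after the result was seen.

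The RNAs most enriched in DMSO EVs included NET1, RAB13, TRAK2 and KIF1C. They code for parts of vesicle traffic, Rho signalling and transport along microtubules, and such mRNAs are known from the protrusions of migrating cells.

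In transcripts of 274 EV-enriched genes there were 20.9 purine-rich windows per kb (50 nt, at least 80% purine), against a median of 3.37 (2.42 to 5.01) in sets matched on length and GC content. Pyrimidine-rich windows numbered 2.78 per kb, against 2.99. Of the EV-enriched genes 72.3% held a purine-rich window, and 46.0% of matched genes did. Purine-rich stretches may thus mark RNAs that EVs take up or keep, a hypothesis found and tested on the same data.

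Of 7 other RNAs known from protrusions 5 were higher in EVs and 0 lower. Their median of 0.859 lay at percentile 96.54 of matched sets (median −0.146), below the upper limit (0.941). KANK2 stood at 3.79, DDR2 at 2.87 and DYNLL2 at 2.25, CYB5R3 at 0.61 ± 0.10 and PKP4 at 0.19 ± 0.07 (SE, n = 3 per group), while INPP1 (adjusted p = 0.0746) and P4HA2 (adjusted p = 0.989) did not pass. Without the RNAs named above, a link of protrusions with EV enrichment beyond matched genes was neither shown nor excluded.

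By gene class, the median log2 fold change between DMSO EVs and cells was 1.79 for processed pseudogenes (667 genes, 431 higher, 34 lower). Their counts may stem from near-identical genes. It was −0.87 for long intergenic noncoding RNAs (786 genes), −0.65 for antisense RNAs (712) and 0.01 for protein-coding genes (13336). By gene length on the genome, the median ran from 0.81 in the shortest of 5 equal groups to −0.89 in the longest.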
